A study of Drosophila melanogaster with 3 samples.

How the data were processed

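Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole adult female Drosophila melanogaster of a transgenic line that carries the zinc finger protein pad fused to GFP at its C terminus. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800, and the fusion protein was recovered with an antibody against GFP. The labels describe 3 biological replicates of 1 group, so that no comparison between groups was made and no sample was left out. Whether each replicate was a separate collection of flies is not stated beyond the word biological, so spreads between replicates cover what differed between these libraries.

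The deposited files are peak lists on the dm6 and dm3 genome builds. Per the deposited lists of derived files, 30000 peaks and background regions were called by the authors on each replicate and on the pooled replicates, each with a control alignment, as input for an analysis of the irreproducible discovery rate (IDR), which compares peak ranks between replicates. The deposited list of peaks that passed IDR held 6659 peaks on dm6 and 7469 on dm3, and each was tested to be the top of the pooled list by signal. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a signal value deposited by the authors, whose scaling is not stated, so it was used only to rank peaks within a list. Each peak also carries a −log10 q-value deposited by the authors, which was read but not used to select peaks. The position of the summit within each peak was taken from the authors' files. Read depth is unknown for all 3 replicates, since the lists hold no read counts, and no interval that needs depth was computed. Exact binomial 95% intervals cover the counting of peaks or genes, not the sequencing depth.

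Coordinates are 1-based on dm6, which is Release 6 of the fly assembly. Start sites, exons and transposable elements came from the gene annotation of Ensembl release 115 on the same assembly, with 23581 distinct start sites and 13945 protein-coding genes on arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were used for counts and overlaps within dm3 only.

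Replicates were compared by the overlap of their top 5000 peaks, where at least 50% of either peak had to be covered, against 100 draws of shuffled positions on the same arms, and by Spearman's rho of signal across IDR peaks. IDR peaks were also sought among the top 10000 peaks of each replicate. The rank and signal of an IDR peak in a replicate were those of the strongest peak there that overlapped it by the same rule. A summit within 250 bp of a start site was called a promoter summit, and shares were set against 100000 random positions drawn in the arm proportions of the IDR peaks and against the pooled peaks that did not pass IDR. Arms were compared by peaks per Mb. A protein-coding gene was called bound when an IDR summit lay within 250 bp of one of its start sites, and 24 gene lists were each tested against all other coding genes. Symbols were matched through current names and unique synonyms, which left 3 listed symbols unmatched. In the 101 bp around each summit, 20 consensus motifs were counted on both strands against windows centred 300 bp to either side. All 8-mers were ranked on 2L and 2R, and the 20 with the smallest p were tested on 3L, 3R and X. Peaks around pad were counted in 50 kb windows.

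Fisher's exact test and exact binomial tests were two-sided, with Benjamini-Hochberg adjustment over the lists, the motifs or the 8-mers and a threshold of 0.05. Peaks, genes and windows are not independent replicates, so these tests describe this set of peaks. Named genes were those at the 25 strongest IDR peaks, pad and each member of the achaete-scute list, and up to 4 bound members of each list with the highest signal, or the first 2 members where none was bound. The gene lists, motifs, tests and most other settings were fixed before the data were examined. Alternatives covered the number of peaks, the overlap rule, the genome build, the distance to a start site, the window width, the background, the strongest 1000 peaks and each replicate left out. For the promoter, arm and motif results 1 summit per merged region, and for the gene lists each replicate list alone and a run without histone genes, were added after seeing the data.

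The procedures were tested on simulated data. Over 20 runs on 13945 genes with 20% of genes bound, lists planted with an odds ratio of 4 were called in 45.0% of cases and other lists in 0%. An 8-mer planted in 3% of 6659 windows ranked first, and 0 words passed with nothing planted. Copied peaks were found in 100% of cases, and 16.0% of peaks that were not copied were also found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.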

Results

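Binding of pad-GFP was profiled by ChIP-seq with an antibody against GFP in whole adult females, in 3 biological replicates. The pad gene (poils au dos) encodes a zinc finger protein known as a repressor of the proneural genes achaete and scute. On dm6 the list of peaks that passed IDR held 6659 peaks in 5579 merged regions, with a median width of 490 bp. The signal of these peaks, the authors' own measure of peak strength, had a median of 498 and reached 97719. The read depth of the replicates is unknown.

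The 25 strongest peaks were found in all 3 replicates, and the first 3 lay near the ends of 2R and chromosome 4 and at the heat shock gene Hsp68. The strongest of all, at 2R:25285149–25286228, was intergenic and had its summit 1299 bp from the end of the assembled arm, with a mean rank of 1.33 ± 0.58 (SD, n = 3) in the replicate lists. Peaks 2 and 9 by signal, at 4:1318232–1319718 and 4:1305777–1307113, lay near the end of chromosome 4 in annotated copies of HeT-A, a retrotransposon that maintains fly telomeres, and ranked 2.67 ± 1.15 and 8.33 ± 2.52 (SD, n = 3). The peak at 3R:24056396–24058444 had its summit 105 bp upstream of Hsp68, an inducible chaperone gene, with a signal of 70685 and a mean rank of 2.33 ± 1.15 (SD, n = 3). Its reads could be shared with related Hsp70 family genes, and the alignment rules are not given in the sources used here.

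Other peaks among the 25 strongest lay in or near crp, Cdk4, 18w, tsh, tio, hth, ssp3 and Clk. The gene crp, which encodes a basic helix-loop-helix factor, held peaks 5 and 8 by signal in its introns, at 2L:16268865–16270110 and 2L:16284137–16285633. Peak 6 by signal lay in an intron of Cdk4, the kinase partner of cyclin D, with its summit 717 bp from the nearest start site, that of asRNA:CR44375. The Toll family receptor gene 18w had summits 286 and 4883 bp upstream of its start site. The teashirt family genes tsh and tio had a summit 132 bp upstream of the start site and in the 3′ UTR, respectively. Introns of hth, a homeobox gene, ssp3 and Clk, the activator of the circadian clock, held peaks 17, 18 and 22 by signal.

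Promoter summits among the 25 strongest also marked Pfas, an enzyme of purine synthesis, stc, beat-Ia, which acts in axon guidance, and Mtr4, an RNA helicase of the exosome, at 6, 46, 202 and 50 bp from the nearest start site. Intergenic summits lay 820 bp from CG33453, 1071 bp from CG11629, 258 bp from CG4565, 1148 bp from CG13891, 2406 bp from CG13321, 408 bp from lncRNA:CR45541 and 13824 bp from CG10651. The peak near lncRNA:CR45541, the only one of the 25 on X, varied most between replicates, with ranks of 40, 14 and 46.

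**Figure D1:**
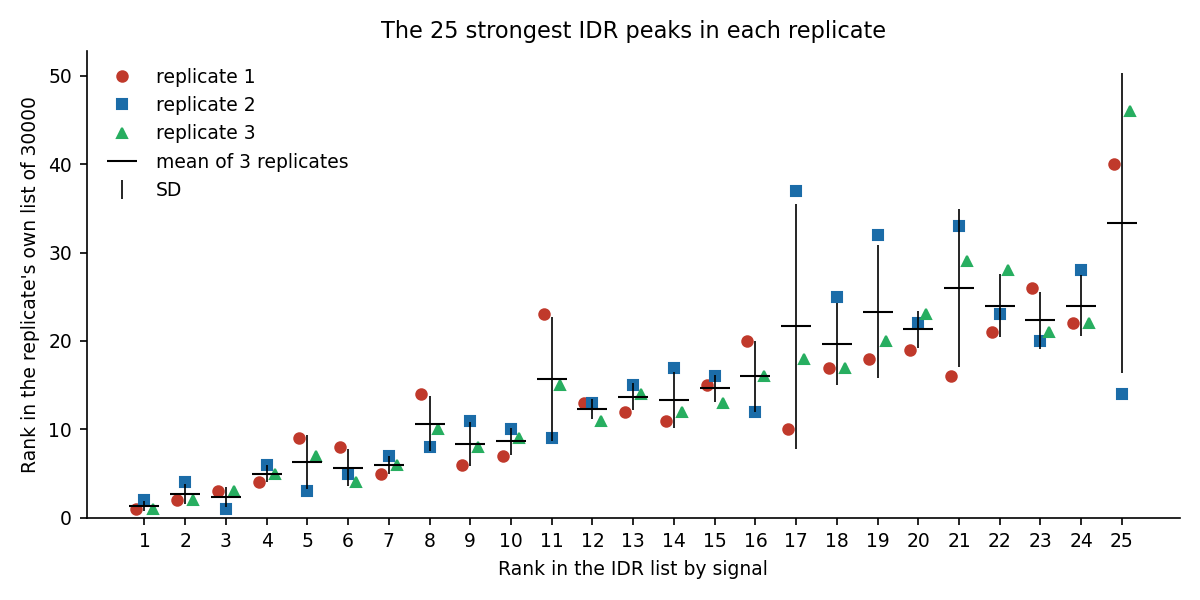
Rank of each of the 25 strongest IDR peaks (x axis, rank by signal in the IDR list) in the replicate's own list of 30000 peaks (y axis), with 1 symbol per replicate, the mean as a horizontal bar and the SD as a vertical line. The first peak ranked 1, 2 and 1 in the replicates, and peak 25 ranked 40, 14 and 46.

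The replicates shared most of their strong peaks. Of the top 5000 peaks, 80.4% were shared between replicates 1 and 2, 81.1% between 1 and 3 and 85.6% between 2 and 3, a mean of 82.4% ± 2.80 (SD, n = 3 pairs). Shuffled positions shared a mean of 2.63%. Signal was also ranked alike across IDR peaks, with a Spearman's rho of 0.747, 0.823 and 0.848 for the same pairs. These correlations are across peaks, which are not independent replicates. The IDR list was itself drawn from these replicates by agreement of their ranks. The correlations and the share of IDR peaks found in every replicate are therefore partly built in, while the overlap of the top 5000 peaks does not use that list. Of the 6659 IDR peaks, 6045 lay among the top 10000 peaks of every replicate (90.8%, exact binomial 95% interval 90.1 to 91.5%). The share fell to 58.7% when only the top 5000 of each replicate were searched, which hold fewer peaks than the IDR list.

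Promoters held about as many IDR summits as all other classes of sequence together. A start site lay within 250 bp of 3262 of the 6659 IDR summits (49.0%, exact binomial 95% interval 47.8 to 50.2%), against 7.54% of random positions and 24.6% of the pooled peaks that did not pass IDR. In the top 5000 peaks of the replicates the promoter share was 49.2% ± 0.52 (SD, n = 3). Introns held 33.2% of IDR summits against 41.4% of random positions, and intergenic sequence 11.3% against 28.0%. Coding exons held 0.886% against 15.1%, and 3′ UTRs 1.01% against 5.53%. The odds ratio of a promoter position was 11.8 against random positions, and 2.94 against peaks that did not pass (Fisher's exact test, p = 5.69e-303 for the latter). The share depended on the distance allowed, with 27.9% within 100 bp and 73.7% within 1000 bp of a start site. Random positions were drawn from the whole assembled sequence of the arms, mappable or not.

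**Figure D2:**
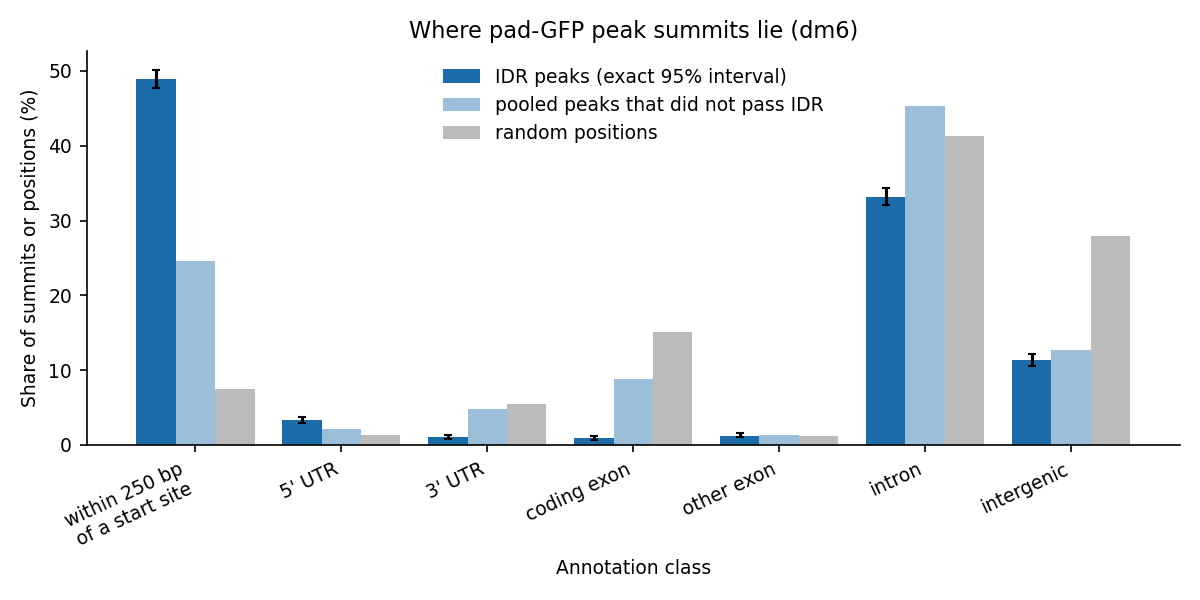
Share of summits or positions (y axis, percent) in each annotation class (x axis) for the IDR peaks, the pooled peaks that did not pass IDR and random positions; error bars on the IDR peaks are exact binomial 95% intervals. Promoters held 49.0% of IDR summits, 24.6% of summits that did not pass and 7.54% of random positions.

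Promoter summits lay mostly on the upstream side of the gene. The nearest start site lay downstream of the summit at 2468 promoter summits and upstream of it at 780, so that 76.0% of summits off the start site itself were upstream of the gene (exact binomial test, p = 3.33e-202). The median offset was -62 bp. Promoters were less frequent among the very strongest peaks, with 33 of the first 100 peaks (33.0%, exact binomial 95% interval 23.9 to 43.1%) against 51.9% of peaks ranked 2001 to 4000 (49.6 to 54.1%). Intergenic summits made up 29.0% of the first 100 peaks.

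The study's target gene had a peak at its own promoter, and the proneural genes of the achaete-scute complex had none. The summit nearest to pad (3R:16342318–16345829) lay 167 bp from its start site, in the peak 3R:16341962–16342369 with a signal of 1381 and an IDR rank of 958. Of all coding genes, 24.4% had an IDR summit this near a start site by the 250 bp rule. The line carries an added tagged copy of pad, so extra copies of this sequence cannot be told apart from binding. No IDR summit lay in or within 1 kb of ac, sc, l(1)sc or ase on X, and the nearest were 63723, 81291, 67630 and 16604 bp from their start sites. Other proneural genes, ato, amos and cato, had their nearest IDR summit 13278, 6106 and 7583 bp from their start sites.

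Of the regulators in the achaete-scute list, emc, da, hry and pnr had promoter summits and ush had none. The gene emc, which encodes a helix-loop-helix antagonist of proneural proteins, had a promoter summit 160 bp upstream of its start site with a signal of 11431. The strongest replicate peaks that overlapped this peak had a mean rank of 30 ± 11.5 (SD, n = 3). In all, emc had 7 IDR summits in the gene or within 1 kb. The promoter summits at da, the partner of proneural proteins, at hry, a repressor of achaete, and at pnr, a GATA factor that activates achaete and scute, had signals of 356, 607 and 403. The pnr partner ush had 7 IDR summits in the gene or within 1 kb. Several summits can lie in the same peak, so the counts for emc and ush are not counts of separate peaks. With 4 of 12 members bound, the achaete-scute list did not differ from other coding genes (odds ratio 1.55, adjusted p = 0.670, Fisher's exact test).

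The sequence around pad was examined because the line carries an added tagged copy of the gene, whose extent the labels do not give. The 50 kb centred on pad held 23 peaks of the pooled list against a median of 9 per window, at the 84.7 percentile of 2668 windows. The replicate lists placed the same window at the 69.7, 87.9 and 79.5 percentile. In a 20 kb window the count was at the 96.3 percentile, and in a 100 kb window at the 59.8 percentile.

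Ribosomal protein genes stood apart from all other lists. Of 92 genes for cytosolic ribosomal proteins, 73 were bound at the promoter (79.3%, exact binomial 95% interval 69.6 to 87.1%), against 24.1% of other coding genes (odds ratio 12.1, adjusted p = 3.73e-27, Fisher's exact test). Those with the highest signal were RpS9, RpS27, RpL7 and RpL27, with signals of 3000, 2953, 2478 and 2284 and mean ranks of 448 ± 250, 350 ± 163, 446 ± 184 and 494 ± 148 (SD, n = 3). Of 20 cell cycle genes 11 were bound (odds ratio 3.79, adjusted p = 0.0194, Fisher's exact test), among them CycB, fzr, Dp and aurA, with signals of 3937, 2223, 1095 and 837. When IDR peaks were kept only if found in replicates 1 and 2, the cell cycle list no longer passed (adjusted p = 0.0783, Fisher's exact test). It passed with the list of replicate 1, 2 or 3 alone (adjusted p = 0.0164, 0.0129 and 0.00994, Fisher's exact test). The range over its alternatives was 0.00108 to 0.387.

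Receptor and histone genes lay at the other end. None of 179 chemosensory receptor genes was bound, Gr10a and Gr10b among them (exact binomial 95% interval up to 2.04%; adjusted p = 2.63e-21, Fisher's exact test). None of 111 replication-dependent histone genes was bound (adjusted p = 3.44e-13, Fisher's exact test), with His1:CG31617 and His1:CG33801 as examples. The histone genes are near-identical copies in which reads cannot be placed uniquely, so their absence from the list is uncertain. For the same reason the 111 genes are not separate observations, and the p-value overstates the evidence. In all, 3407 of 13945 coding genes were bound (24.4%), and 4 of the 24 lists passed, 2 with a higher and 2 with a lower share. With a distance of 1000 bp 10 lists passed, with the 1000 strongest peaks 2, and without the histone genes 3.

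The other lists did not pass the test as reported, and some did under another rule. Polycomb and trithorax group genes were bound in 10 of 20 cases (adjusted p = 0.0704, Fisher's exact test), including ph-d with a signal of 11535, brm, E(z) and Sfmbt. This list passed with each replicate list alone (adjusted p = 0.0164, 0.0129 and 0.00268), within 1000 bp of a start site (0.00487) and in the gene or within 1000 bp (0.00136, all Fisher's exact test). Genes of nuclear-encoded oxidative phosphorylation were bound in 30 of 84 cases (adjusted p = 0.0726, Fisher's exact test), with COX7C at a signal of 9858 and ND-42, COX6B and ND-B22 at 1271, 1269 and 971. Proteasome genes were bound in 13 of 34 cases, among them Rpt5, Rpn5, Rpn2 and Rpn3 (adjusted p = 0.156, Fisher's exact test). Neither Jonah midgut proteases (0 of 16), such as Jon25Bi and Jon25Bii, nor photoreceptor genes (0 of 15), such as ninaE and Rh2, had a bound member, with adjusted p of 0.0704 and 0.0898 (Fisher's exact test). Yp3 was the 1 bound gene of 20 for eggshell and yolk (adjusted p = 0.104, Fisher's exact test).

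Among regulators and tissue genes, bound insulator genes were Chro, Cp190, Dref and BEAF-32 in a list with 6 of 14 bound, and bound clock genes were sgg, tim, vri and per in a list with 5 of 10. The odds ratio of the clock list was 3.10 as reported, 17.9 within 1000 bp (adjusted p = 0.00179) and 32.7 in the gene or within 1000 bp (adjusted p = 0.000508, both Fisher's exact test), but 0.766 with replicate 1 alone. The insulator list also passed within 1000 bp (adjusted p = 0.0225) and in the gene or within 1000 bp (adjusted p = 0.00996, both Fisher's exact test). The fat body and metabolism list had 6 of 14 bound, with Lpin, Thor, InR and bmm strongest, and the nuclear pore and lamina list 9 of 25, with Lam, Nup37, Nup43 and Nup160. RpS27 and Nup37 share a summit, as do ChAT and VAChT. The ecdysone list had 5 of 15 bound (ftz-f1, dib, Eip74EF, Eip75B), the Notch list 6 of 18 (numb, gro, Su(H), neur) and the germline list 6 of 19 (osk, ovo, grk, bgcn). Developmental signalling genes were bound in 5 of 18 cases (spi, en, inv, ci), innate immunity genes in 6 of 23 (imd, cact, spz, Rel) and heat shock genes in 4 of 14 (Hsp68, Hsp27, Hsp83, Hsp26). Neuronal genes (Syt1, ChAT, VAChT) and muscle genes (Tm1, Prm, Mef2) each had 3 of 16 bound, and Hox genes 1 of 8 (Scr). Adjusted p for these lists lay between 0.156 and 0.811 (Fisher's exact test).

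**Figure D3:**
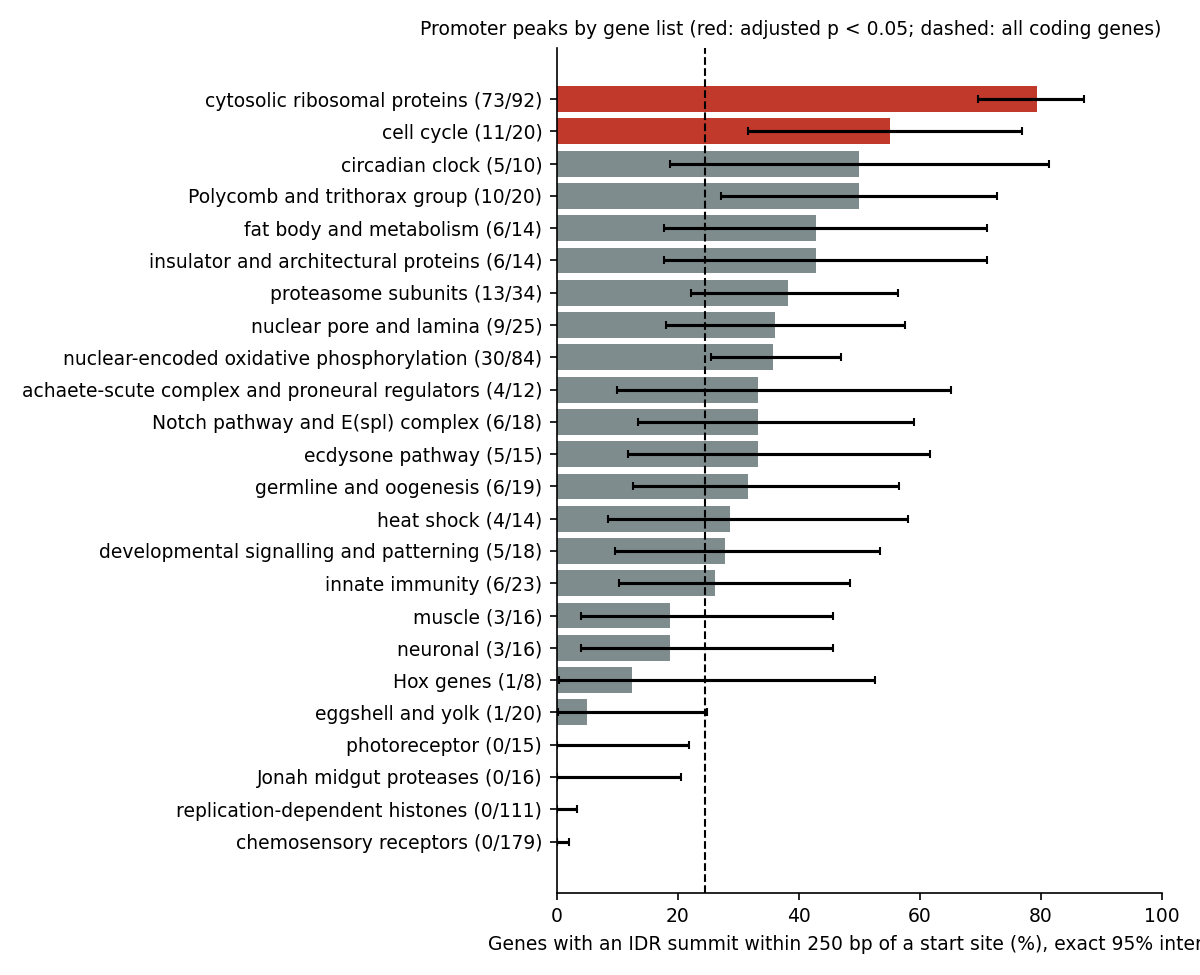
Share of the genes of each list with an IDR summit within 250 bp of a start site (x axis, percent; bars with exact binomial 95% intervals), with bound and total members after each list name. Red bars passed the adjusted threshold, and the dashed line marks the 24.4% of all coding genes; ribosomal protein genes reached 79.3%.

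The X chromosome held more IDR peaks per Mb than the autosomes, and chromosome 4 fewer. X carried 1440 peaks or 61.2 per Mb, against 46.9 on 2L, 49.9 on 2R, 45.0 on 3L, 48.6 on 3R and 21.5 on chromosome 4. The ratio of X to the 4 large autosome arms was 1.28 per Mb (exact binomial test, p = 2.32e-16) and 1.47 per coding gene. In the top 5000 peaks of each replicate the ratio was 1.30 ± 0.045 (SD, n = 3).

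**Figure D4:**
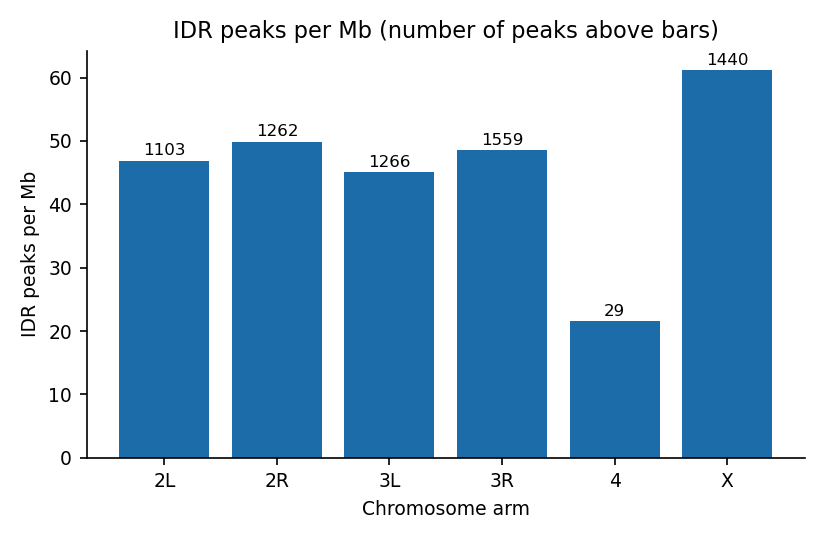
IDR peaks per Mb (y axis) on each chromosome arm (x axis), with the number of peaks above each bar. X had 61.2 peaks per Mb and chromosome 4 had 21.5.

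Sequence outside these arms was represented in the dm3 lists alone. The dm6 lists held peaks on 2L, 2R, 3L, 3R, 4 and X only. The dm3 pooled list had 54 of 30000 peaks on heterochromatic or unplaced sequence (0.180%, exact binomial 95% interval 0.135 to 0.235%) and the dm3 IDR list 10 of 7469, of which 4 were on Uextra, 3 on U and 1 each on 2RHet, 3LHet and XHet. The strongest of these, at U:7457877–7458337 on dm3, ranked 57 in the dm3 IDR list.

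Motifs of promoter and insulator factors were more frequent at IDR summits than 300 bp away. Motif 7 of the core promoter set occurred at 508 summits (7.63% against 3.51% of flanks, odds ratio 2.27, adjusted p = 9.25e-34), and the core of the insulator factor CTCF at 92 (1.38% against 0.285%, odds ratio 4.90, adjusted p = 2.97e-17, both Fisher's exact test). The DRE, bound by DREF and BEAF-32, was found at 2.21% of summits against 0.766% of flanks (odds ratio 2.92), and the GAGA factor site at 5.86% against 3.63% (odds ratio 1.65). Against windows at the same distance from start sites without an IDR peak these odds ratios were 1.71 and 3.36, so that their order was reversed. The BEAF-32 core, Motif 1, Motif 5, the E-box CAGCTG, Motif 6 and the Su(Hw) core also passed, with odds ratios from 1.21 to 2.38. The Su(H) site was less frequent, at 0.751% against 1.10% (odds ratio 0.683, adjusted p = 0.0401, Fisher's exact test). This call was lost with 100 bp either side (odds ratio 0.960, adjusted p = 0.744), against start-site-matched windows (0.760, adjusted p = 0.0842), with 1 summit per merged region (0.762, adjusted p = 0.185) and in the top 1000 peaks (1.00, adjusted p = 1, all Fisher's exact test).

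The other 9 of the 20 motifs, among them the Initiator (odds ratio 0.991) and the TATA box (0.995), did not pass. Against windows at the same distance from start sites without an IDR peak, the TATA box (odds ratio 0.556, adjusted p = 3.42e-08, Fisher's exact test) and the Initiator (0.841, adjusted p = 2.52e-07) were less frequent at IDR summits. In the 1000 strongest peaks 2 motifs passed, Motif 7 and the GAGA factor site, where the CTCF core had an odds ratio of 2.26 (adjusted p = 0.593, Fisher's exact test).

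All 20 words of 8 bases found on 2L and 2R were also more frequent at summits on 3L, 3R and X. CAACACTG led, at 2.72% of 4265 summits against 0.399% of flanks (odds ratio 6.99, adjusted p = 2.86e-27, Fisher's exact test), followed by odds ratio by AGTGTTGG, with which it overlaps on the opposite strand, at 1.71% against 0.340%. A separate group of words shared a run of G, with AGGGGAAA at 2.86% against 0.574% (odds ratio 5.10, adjusted p = 2.83e-23, Fisher's exact test) and GAGGGGAA at 1.66% against 0.363%. The word GAGCGAGA occurred at 3.31% of summits against 1.52%, and TATCGATA, which is the DRE, at 2.39% against 0.856%. With discovery and test arms exchanged, 18 words passed and 11 of the 20 were the same.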

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

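All alternatives below that use 1 summit per merged region, a replicate list alone or no histone genes were chosen after seeing the data. The promoter share, the odds ratio of promoters against peaks that did not pass and the X ratio kept their direction and their side of the threshold under every alternative run for them, although the promoter share of 49.0% ranged from 27.9% to 73.7% and the X ratio from 1.23 to 1.48. The count of 8-mers was between 14 and 20, with 14 for 25 bp either side, and the share outside the main arms was 0.160% in the alternative against 0.180%. Over all main results 49 values under another setting kept and 20 moved. For promoter, arm, gene list and motif results, leaving out a replicate kept most of the IDR peaks, so little change was built in. No paired analysis was possible because the samples form 1 group. Read depth is unknown, so its effect on weak peaks was not examined.

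Replicate overlap was 79.1% with the top 10000 peaks and 73.2% with summits within 100 bp, and 80.4% to 85.6% with each replicate left out. The rank correlation of signal between replicates ranged from 0.747 to 0.848 with each replicate left out. IDR peaks found in every list made up 58.7% with the top 5000, fewer than the IDR peaks by construction, 97.3% with all listed peaks, 92.4% with any overlap of 1 bp, 84.8% in dm3 and 92.3% to 94.5% with a replicate left out, where fewer lists were required. Lists past the threshold numbered 10 within 1000 bp, 10 with the gene and 1000 bp around it, 2 in the top 1000 peaks and 7 with replicate 1 or replicate 2 alone. Motifs past the threshold numbered 2 in the top 1000 peaks. The pad window lay at the 96.3 percentile with 20 kb, 59.8 with 100 kb and 69.7 in replicate 1. For overlap rules, distances, builds and window sizes the cause was not tested; the top 1000 peaks test fewer peaks.

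Of 15 called lists and motifs, 111 values kept their call, 14 lost it and 2 turned. Those 2 were Motif 6 (odds ratio 0.788) and the Su(Hw) core (0.923) in the top 1000 peaks, neither of them called there. Of 29 uncalled lists and motifs, 217 values stayed uncalled in the same direction, 28 gained a call and 27 crossed an odds ratio of 1. Besides the Polycomb, clock and insulator lists, calls were gained within 1000 bp by germline (adjusted p = 0.0295), Jonah (0.00782) and nuclear pore genes (0.0246, all Fisher's exact test). In the gene or within 1000 bp they were gained by ecdysone (adjusted p = 0.00566), Jonah (0.00178) and nuclear pore genes (0.00499), with replicate 1 alone by oxidative phosphorylation and eggshell genes (both 0.0243), and with replicate 2 alone by proteasome (0.0478) and ecdysone genes (0.0129, all Fisher's exact test). In the top 1000 peaks those that crossed were Hox genes (1.57), oxidative phosphorylation (0.321), proteasome (0.386), neuronal (1.78), ecdysone (0.860), the GATA factor (0.884), the TATA box (1.40) and the heat shock element (1.19). With the gene and 1000 bp around it they were Hox genes (1.55) and innate immunity (0.828), and within 1000 bp developmental signalling (0.990). With replicate 1 alone they were Hox genes (1.02), developmental signalling (0.875), circadian clock (0.766) and innate immunity (0.645). Innate immunity had 0.662 with replicate 2 alone and 0.920 with replicate 3 alone, where neuronal genes had 1.10. With 100 bp either side they were AP-1 (0.961), the TATA box (1.15) and the Initiator (1.02). The TATA box had 1.08 with 1 summit per merged region and 1.02 to 1.07 with a replicate left out, and the E-box CACGTG 0.982 to 1.02. The cause was not tested.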

Other observations

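The tests of extra telomeric copies, of summit precision, of X at every level and of the achaete-scute interval were chosen after the result was seen; the tests of other transposable elements, of promoters and of GA repeats were written before theirs. The genes with the most summits and the classes of noncoding genes described here were also chosen after their values were seen.

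Some coding genes carried many IDR summits. The genes named here were picked from those with the most, and no class of gene was tested. Others with 10 or more included klar (11), Svil (10) and Tm1 (10). Tlk, a chromatin kinase gene on X, had 21 in the gene or within 1 kb, and psq, a BTB domain factor, had 20. Eip74EF and Eip75B, early genes of the ecdysone response, had 18 and 16, the clock gene Pdp1 had 17, the insulin receptor gene InR had 14, and Trl, which encodes GAGA factor, had 10. In Trl the density was 6.61 per 10 kb and in Mnt on X, a bHLH factor gene with 17 summits, 5.33 per 10 kb, against 0.497 per 10 kb over all arms. In pum, a gene of 171 kb with 11 summits, it was 0.635 per 10 kb, so counts partly reflect gene length. Summits of the same peak were counted separately, and 1104 IDR summits shared their peak interval with another. These counts and densities are therefore not those of separate peaks. Of the 34 coding genes with 10 or more summits, 10 were on X, which holds 2196 of the 13945 coding genes. X also held more IDR peaks per Mb than the autosomes, and the difference in these counts was not tested. At the other end, 8482 coding genes had no IDR summit in the gene or within 1 kb.

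Noncoding genes are set beside the 24.4% of coding genes that were bound, without a test of the differences. An IDR summit lay at the start site of 20 of 290 tRNA genes (6.90%, exact binomial 95% interval 4.26 to 10.5%), 12 of 269 snoRNA genes (4.46%) and 207 of 3261 other noncoding RNA genes (6.35%). Genes for snRNA were bound in 7 of 32 cases (21.9%, exact binomial 95% interval 9.28 to 40.0%, which contains 24.4%), and 0 of 99 rRNA genes were bound. Repeated copies of tRNA, snRNA and rRNA genes share reads, so these shares are uncertain.

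Some of the strongest peaks lay in telomeric sequence. Peaks 2 and 9 of the 25 strongest were in HeT-A copies on chromosome 4, and 24.98% of the 16-mers of the first peak, at the end of 2R, also occurred in annotated HeT-A. Telomeric elements held 4 IDR summits in all, at 0.761 times the density outside elements (exact binomial 95% interval 0.207 to 1.95, p = 0.826), and 98 of the first 100 IDR summits lay outside annotated elements. IDR peaks did not pile up in repeated sequence of every kind. Transposable elements other than telomeric ones held 8 IDR summits in 7.84 Mb, a density 0.0193 times that outside elements (exact binomial test, p = 8.80e-159). The alignment rules are not given, and reads that match several places may have been dropped. This density therefore cannot decide whether the telomeric peaks arose from read placement. More telomeric copies in the flies than in the assembly may also raise such peaks, and this stays open: AGGGGAAA lay within 50 bp of 2 of 10 summits of the pooled list in telomeric elements against 2.73% of random positions there (odds ratio 8.91, Fisher's exact test, p = 0.0293). Because the test rests on 2 summits in related copies, a minimum of 5 was set after its value was seen, and the explanation cannot be told apart from binding. The design has 1 group, and no biological explanation was tested.

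The word AGGGGAAA was concentrated in the strongest peaks: it lay within 50 bp of the summit in 29 of the first 100 IDR peaks and in 1.47% of those ranked 4001 to 6659. Of the 25 strongest peaks, 14 had it within 50 bp of the summit and 19 anywhere in the peak, a wider search without a background. GAGCGAGA also declined, from 10 of the first 100 to 2.29% at ranks 4001 to 6659, so the trend was not specific to AGGGGAAA. CAACACTG was found at 1 of the first 100, 4.10% of peaks ranked 2001 to 4000 and 2.41% of those ranked 4001 to 6659. A larger share of promoters among weaker peaks is argued against as the whole cause, since within promoter summits the word was also more frequent in the top 1000 than in other IDR peaks (6.49% against 0.888%, odds ratio 7.74, Fisher's exact test, p = 2.47e-12). Less exact summits in weaker peaks are argued against as the whole cause for shifts of up to 250 bp, since within 250 bp of summits on 3L, 3R and X the word was still more frequent in the top 1000 (11.5% against 4.16%, odds ratio 2.98, Fisher's exact test, p = 7.04e-12). Among summits there without the word within 50 bp, 4.08% of the top 1000 and 2.19% of the others had it within 250 bp (odds ratio 1.90, Fisher's exact test, p = 0.00936). A part played by summit precision stays open. On those arms and within 50 bp GAGCGAGA was also more frequent in the top 1000 (odds ratio 2.09, adjusted p = 0.00110, Fisher's exact test). CAACACTG went the other way and was less frequent there (odds ratio 0.304, adjusted p = 0.00313, Fisher's exact test). A hypothesis is that AGGGGAAA may be part of a sequence pad-GFP recognises, which was not tested, since flies without the fusion were not analysed here.

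The excess of IDR peaks on X was also partly present below the IDR threshold, where the ratio to autosomes was 1.14 per Mb (exact binomial 95% interval 1.10 to 1.18) against 1.28 (1.21 to 1.36) above it. The X share was higher among IDR peaks than among those that did not pass (odds ratio 1.13, Fisher's exact test, p = 0.000400). This difference was smaller with 1 peak per merged region (odds ratio 1.10, p = 0.0138, Fisher's exact test), a requirement added after the first value was seen. Both sets were cut by signal from the same list, so a general rise of signal on X could also give the difference. More calls on X at every level therefore stay open as a cause. Summits that carry GAGAGAG are argued against as the whole cause, since without them the ratio was 1.28 (exact binomial test, p = 2.27e-15). Among summits with GAGAGAG the ratio was 1.31 (exact binomial 95% interval 1.02 to 1.67). They made up only 5.86% of IDR summits, so leaving them out was a weak test of GA repeats. Shorter GA runs, GA repeats farther from the summit and the control alignment stay open. No biological explanation was tested.

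A hypothesis was that pad-GFP lies between the achaete-scute genes in place of their promoters. The 93.1 kb from ac to ase (X:370031–463176) held 0 IDR summits and 1 peak of the pooled list, against a median of 3 IDR summits in 1428 windows of that size. The empty interval already follows from the distances to sc and l(1)sc given above, so it is not a separate test. The hypothesis of IDR peaks between these genes was not borne out in whole adult females, and other stages were not examined. As few summits were found in 24.4% of windows, so the interval was not unusual. Binding in a small number of cells of the whole fly would not be detectable here.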
